A study of Mus musculus with 16 samples.

How the data were processed

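Platelets of male mice aged 10 to 12 weeks were freed of leukocytes by immunomagnetic negative selection, per the labels. miRNA libraries were made from 10 to 20 ng of RNA with the QIAseq miRNA kit and sequenced in pairs on a NovaSeq6000. Per the labels the samples form 4 groups of 4: WT (Dicer lox/lox) and KO (Dicer deleted through Pf4), each at baseline and after infarct. The submitters' processing notes name FastQC 0.11.8, Trim Galore 0.6.3, Bowtie 1.3.0, SAMtools 1.10.2, edgeR 3.11 and the genome GRCm38, without their roles or order. The handling of unique molecular identifiers, the mismatches allowed, reads that map to several places and the miRBase release are not given in the sources used here.

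The authors deposited 3 pairwise tables of whole-number counts per mature miRNA, which were the input of every test here. Where these count tables shared libraries, 76640 cells were compared, 76640 were equal and 0 differed. They name 1915 miRNAs and 1 entry without a name, which held 0 reads (0%) and was left out; 993 miRNAs had at least 1 count and 487 at least 100 counts in all. The authors' tables of TMM-scaled CPM hold the 427, 443 and 400 miRNAs that passed their filter and 99.98% of the counts of each pair. Those CPM were checked against the counts and not tested. The mature length that the authors list ranged from 15 to 27 nucleotides and was used for the relation of fold change with length alone. The authors' FPKM and TPM tables were left out, because a length correction has no use for mature miRNAs, as was a text table whose values are CPM despite its name. Reads were not remapped. In 7 sets, 15 miRNAs had identical counts in every library, among them miR-486a-5p with miR-486b-5p, and each set carries the evidence of a single measurement.

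Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, two-sided, TMM factors, filterByExpr) with Benjamini-Hochberg adjustment within each comparison, and an adjusted p under 0.05 was called. KO against WT at baseline and infarct against baseline in WT and in KO were fitted on the 8 libraries of each pair, which the authors' tables also join. KO against WT after infarct and the interaction were fitted on all 16 libraries. The SE is the absolute log2 fold change divided by the square root of F. Levels are CPM scaled with TMM within each fit, given as mean and SD; the baseline WT markers and the panels of levels use the fit of all 16, and shares in percent and all miR-451a levels use plain library totals. A log2 CPM of one library used a pseudocount of 1. Groups of 4 and 4 allow no exact permutation p under 0.0286.

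miRNAs were named by a rule set before their values were seen: the 10 largest calls in each direction with a mean of at least 100 CPM, the 10 most abundant in baseline WT, and 9 fixed miRNAs (miR-451a, miR-223-3p, miR-126a-3p, miR-21a-5p, miR-191-5p, miR-150-5p, miR-122-5p, miR-1a-3p and let-7a-5p). Members of the fixed lists serve as examples of their list, and where fewer than 5 miRNAs passed the 5 with the smallest p were named. The fixed lists numbered 21, covering cell markers, families and clusters, and ways of biogenesis, and each was counted within the whole comparison and adjusted over the list alone. Lists with at least 3 tested members were tested with camera (limma 3.58.1, correlation between miRNAs fixed at 0.01), with camera at an estimated correlation, and with fry. The list of miRNAs made without Dicer held miR-451a alone and passed in 0 comparisons. Hairpins were placed with GENCODE M21 on GRCm38, which located 77 of 77 named and 481 of 495 tested miRNAs.

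Alternatives set in advance were DESeq2 1.42.0, limma-voom, RLE factors, library totals only, scaling to miR-451a, miR-451a left out, no filter, a minimum of 100 CPM in 4 libraries, the other set of libraries in the fit, a block for the replicate number and each library left out. Identical miRNAs counted once and counts thinned to one depth were added after the data were seen. Replicates differed far beyond counting error, with a chi-square per degree of freedom of 32.2 to 889 over 24 pairs (miRNAs with at least 20 counts), so counting error alone understates the spread between libraries. Fits were tested on simulated data. Recovered shares count only the changed miRNAs that passed the filter, so shares of all changed miRNAs are lower. Recovered shares of 2-fold changes were 67.8%, 54.1%, 65.6% and 43.5% (KO against WT at baseline, infarct in WT, infarct in KO, KO against WT after infarct). False shares were 0.877%, 2.78%, 0.952% and 2.56%, and 0 calls were made when nothing was changed. Permutations numbered 100000 (smallest possible p 1e-05) and shuffles and resamples 10000 (smallest possible p 0.0001). Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.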

Results

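Small RNA libraries were made from platelets, the blood cells without a nucleus that megakaryocytes shed, of male mice aged 10 to 12 weeks. The mice either carried floxed but intact alleles of Dicer, the enzyme that cuts most hairpin precursors to mature miRNAs (WT), or had lost Dicer in megakaryocytes and platelets through a Pf4-driven deletion (KO). Each genotype was sampled at baseline and after an infarct, with 4 libraries in each of the 4 groups and 16 in all. The labels give neither the organ nor the time of the infarct, and they do not say that replicates came from separate animals, so the p-values measure the spread between these samples. They name no batch of preparation or sequencing, so a batch that coincided with infarct or genotype cannot be told apart from it. Libraries held 3742122 to 12107356 miRNA counts. The mean totals in M counts were 7.91 ± 0.21 in baseline WT, 6.88 ± 0.28 in baseline KO, 10.4 ± 2.68 in infarct WT and 7.53 ± 2.88 in infarct KO (SD, n = 4). A library held between 478 and 624 different miRNAs, on average 598 ± 19.4 in baseline WT, 534 ± 36.7 in baseline KO, 588 ± 19.6 in infarct WT and 490 ± 10.0 in infarct KO (SD, n = 4). The deleted gene could not be checked, because Dicer mRNA is not measured by a table of miRNA counts. All levels are relative to the other miRNAs of the same library, so a loss shared by every miRNA would not be seen.

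The let-7 family, whose members share one seed sequence, dominated platelet miRNA. Its 9 guide strands made up 61.0% ± 2.35 of the counts in baseline WT, 61.6% ± 2.24 in baseline KO, 60.0% ± 2.44 in infarct WT and 53.9% ± 2.88 in infarct KO (SD, n = 4). In baseline WT let-7a-5p led with 15.0% ± 0.62 of the counts, followed by let-7c-5p (13.6%), let-7i-5p (10.6%), miR-191-5p (10.1%) and miR-16-5p (9.85%). let-7f-5p, let-7b-5p, miR-328-3p, miR-128-3p and miR-26a-5p completed the 10 most abundant. The 10 most abundant miRNAs of each library itself together held 83.4% ± 0.85 of its counts in baseline WT (SD, n = 4). Several markers of other cells lay far lower than miR-223-3p in baseline WT, others less so. The hepatocyte miRNA miR-122-5p stood at 13.6 ± 3.98 CPM, the muscle miRNA miR-1a-3p at 29.7 ± 5.40 CPM, the lymphocyte miRNA miR-150-5p at 276 ± 32.4 CPM and the smooth muscle miRNA miR-143-3p at 109 ± 11.5 CPM, against 2780 ± 267 CPM for miR-223-3p, which is abundant in both platelets and granulocytes (SD, n = 4). Over the 8 WT libraries of both conditions, the red cell miR-486a-5p averaged 780 CPM and the endothelial miR-126a-3p 454 CPM. miR-223-3p averaged 3288 CPM there (scaled within that fit). miR-486a-5p was lower after infarct, so its mean in baseline WT lay above this average. miR-451a, which is matured by Ago2 without Dicer and is abundant in red cells, had only 0 to 75 counts per library. How the kit and the mapping treat red cell miRNAs is not given in the sources used here, so these counts do not measure red cell content. Its share was 3.02 ± 2.31 CPM in baseline WT, 3.90 ± 3.38 in baseline KO, 2.58 ± 3.13 in infarct WT and 3.44 ± 3.14 in infarct KO (SD, n = 4). The 4 differences between groups were 0.885 CPM for KO over WT at baseline, -0.435 for infarct over baseline in WT, -0.460 in KO and 0.859 for KO over WT after infarct. Two-sided exact permutation p were 0.629, 0.8, 0.771 and 0.629, with an adjusted p of 0.8 for each, and 0.0286 is the smallest p that 4 against 4 libraries allow. The counts were 0 in baseline KO 3 and infarct KO 3, which allows up to 0.553 and 0.540 CPM (exact 95% Poisson limits, for counting error only).

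The first comparison asked how platelet miRNAs differ between KO and WT at baseline. In KO platelets, miR-326-3p, which lies in an intron of Arrb1, fell 2.997-fold from 292 ± 59.7 to 97.4 ± 13.2 CPM, and miR-128-3p, a miRNA best known from neurons, fell 2.48-fold from 17167 ± 582 to 6923 ± 494 CPM (SD, n = 4). let-7i-5p fell 2.07-fold from 106543 ± 7476 to 51433 ± 1813 CPM, while the more abundant let-7a-5p lay at 151060 ± 13996 and 159901 ± 8542 CPM with an adjusted p of 0.552 (SD, n = 4). Among the miRNAs that rose, miR-296-3p went from 134 ± 16.3 to 266 ± 33.5 CPM and miR-155-5p, which acts in activated lymphocytes and macrophages, from 330 ± 67.2 to 656 ± 92.2 CPM, both 1.99-fold (SD, n = 4). In each of these 5 changes all 4 KO libraries lay on the same side of the WT median.

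The log2 fold changes were -1.58 ± 0.15 for miR-326-3p (adjusted p = 3.25e-07), -1.31 ± 0.09 for miR-128-3p (3.62e-09), -1.05 ± 0.08 for let-7i-5p (2.11e-08), 0.99 ± 0.13 for miR-296-3p (1.54e-05) and 0.99 ± 0.15 for miR-155-5p (4.54e-05), each ± SE. The other large falls were those of miR-29b-3p, known to target collagen transcripts (-1.26 ± 0.14), miR-185-5p (-1.22 ± 0.11), miR-339-5p (-1.06 ± 0.14), miR-99b-5p (2.01-fold), miR-301a-3p (-0.98 ± 0.16), miR-151-3p (-0.89 ± 0.11) and miR-484 (-0.88 ± 0.17). The other large rises were those of miR-140-3p, known from cartilage (0.95 ± 0.15), miR-196b-5p, encoded in a Hox cluster (0.87 ± 0.12), miR-26b-5p (0.82 ± 0.16), miR-466f-3p (0.74 ± 0.13), miR-466i-5p (0.73 ± 0.13), miR-672-5p (0.72 ± 0.14), miR-34a-5p, a p53 target (0.71 ± 0.15), and miR-31-5p (0.68 ± 0.13). miR-21a-5p, which is induced in many injured tissues, fell by 0.58 on the log2 scale, and miR-328-3p fell by 0.41. let-7c-5p and let-7b-5p rose by 0.36 each and miR-150-5p by 0.41. miR-191-5p (0.03 ± 0.09), miR-16-5p (0.21 ± 0.08, adjusted p = 0.0724), let-7f-5p (-0.04 ± 0.09), miR-26a-5p (0.04 ± 0.10), miR-223-3p (-0.01 ± 0.10) and the endothelial miR-126a-3p (0.15 ± 0.10) did not pass. Neither did miR-122-5p (0.22 ± 0.29), miR-1a-3p (0.22 ± 0.22) or miR-451a (0.30 ± 0.91).

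Mature miRNAs were placed on GRCm38 by their hairpin genes, with 1-based positions. A hairpin was placed in an exon when an exon of any annotated transcript of the host overlapped it. Such a hairpin can still lie in an intron of the host's other transcripts. Mir326 lies on chromosome 7 from 99552269 to 99552363 on the plus strand in an Arrb1 intron, Mir185 on chromosome 16 from 18327401 to 18327465 on the minus strand in a Tango2 intron, and Mirlet7i on chromosome 10 from 122985640 to 122985724 in no annotated host gene. miR-128-3p has 2 source hairpins, Mir128-1 in an R3hdm1 intron (chromosome 1, 128202361 to 128202430) and Mir128-2 in an Arpp21 intron (chromosome 9, 112118636 to 112118711), which its counts cannot separate. Mir155 lies in an exon of its host RNA Mir155hg (chromosome 16, 84714140 to 84714204), Mir296 outside any annotated host gene (chromosome 2, 174267047 to 174267125), Mir140 in an exon of Wwp2 (chromosome 8, 107551244 to 107551313) and Mir21a in an exon of Vmp1 (chromosome 11, 86584067 to 86584158).

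Among the fixed lists at baseline, the lymphocyte list stood out, with 3 of 6 tested members higher in KO, 0 lower and 3 not passing. These were miR-155-5p, miR-150-5p and miR-181a-5p (0.40 ± 0.10), and adjusted over the list alone 5 were higher. camera gave an adjusted p of 0.0375 (upward), which was lost with an adjusted p = 0.535 with an estimated correlation and 0.0630 with a replicate block. The 9 let-7 guide strands split, with let-7b-5p and let-7c-5p higher, let-7i-5p, miR-98-5p (-0.68 ± 0.11), let-7e-5p (-0.57 ± 0.09) and let-7d-5p (-0.27 ± 0.09) lower and 3 not passing (camera adjusted p = 0.318). Adjusted over the list alone the let-7 counts were 2 higher and 4 lower. Of the miR-23, miR-27 and miR-24 clusters, 4 of 8 members were lower and 0 higher, led by miR-27a-3p (-0.81 ± 0.10) and miR-24-3p (-0.76 ± 0.10), and 4 were lower adjusted over the list alone (camera adjusted p = 0.151). Of 15 members of the miR-17 to miR-92 clusters, which promote proliferation, 4 were higher, among them miR-92a-3p and miR-25-3p (0.59 ± 0.10 each), 0 were lower and 11 did not pass. Adjusted over the list alone 4 of these clusters' members were higher (camera adjusted p = 0.0933). miRNAs known as abundant in platelets went both ways, with 5 of 25 higher, 7 lower and 13 not passing, and 5 and 7 adjusted over the list alone (camera adjusted p = 0.789). In the inflammation and hypoxia list, 3 of 9 were higher (miR-155-5p, miR-34a-5p and the NF-kappaB target miR-146a-5p at 0.60 ± 0.11) and 2 lower (miR-21a-5p and its passenger strand miR-21a-3p at -1.93 ± 0.35), with the same counts adjusted over the list alone (camera adjusted p = 0.758). Members of the Sfmbt2 repeat cluster, whose near-identical sequences make single members uncertain, were higher for 3 of 45 and lower for 1, and higher for 3 and lower for 0 adjusted over the list alone (camera adjusted p = 0.243).

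Of 8 red cell miRNAs 0 passed at baseline (camera adjusted p = 0.545), 0 adjusted over the list alone, and of 3 liver miRNAs 0 passed (0.789). Of 5 myeloid miRNAs miR-146a-5p was higher and miR-223-5p (-0.37 ± 0.12) lower (0.897). Of 4 endothelial miRNAs miR-221-3p was lower (-0.36 ± 0.10; 0.758), and of 2 stromal miRNAs, both below 0, miR-143-3p fell from 103 ± 11.1 to 38.2 ± 6.34 CPM (log2 -1.42 ± 0.16, levels ± SD, n = 4). The 2 tested muscle miRNAs did not pass. Among families, miR-15b-5p (0.60 ± 0.10) was the member that passed of 5 in the miR-15 and miR-16 family, with 2 higher adjusted over the list alone (camera adjusted p = 0.261), and miR-29b-3p that of 3 in the miR-29 family (0.545). miR-99b-5p was the member that passed of 4 in the miR-99, miR-100 and miR-125 list (0.545), and 0 of 7 miR-30 members passed (0.758). Of 6 miRNAs made without Drosha, which still need Dicer, miR-484 and miR-1981-5p (-0.83 ± 0.11) were lower (0.27), as was miR-1839-5p (-0.59 ± 0.13) of 3 miRNAs from snoRNAs (0.545). In the imprinted Dlk1-Dio3 cluster 0 of 3 passed (0.95), and its camera direction (up) differed from its median (-0.83) and mean (-0.25).

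edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 47 miRNAs higher and 55 lower in KO of 427 tested at baseline. Of these calls 27 changed more than 2-fold, 7 of them with a mean of at least 100 CPM. Groups of 4 against 4 did not overlap for 114 miRNAs (26.7%), where chance gives 2.86%. In one fit of all 16 libraries 25 were higher, and miR-296-3p, miR-328-3p, let-7b-5p, let-7c-5p and miR-150-5p did not all pass in every setting tried. With a library left out, 10 of the 37 list members that passed lost their call at least once, among them miR-150-5p, miR-223-5p, miR-221-3p, miR-23a-3p, miR-23a-5p, let-7b-5p, let-7c-5p and let-7d-5p.

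**Figure D1:**
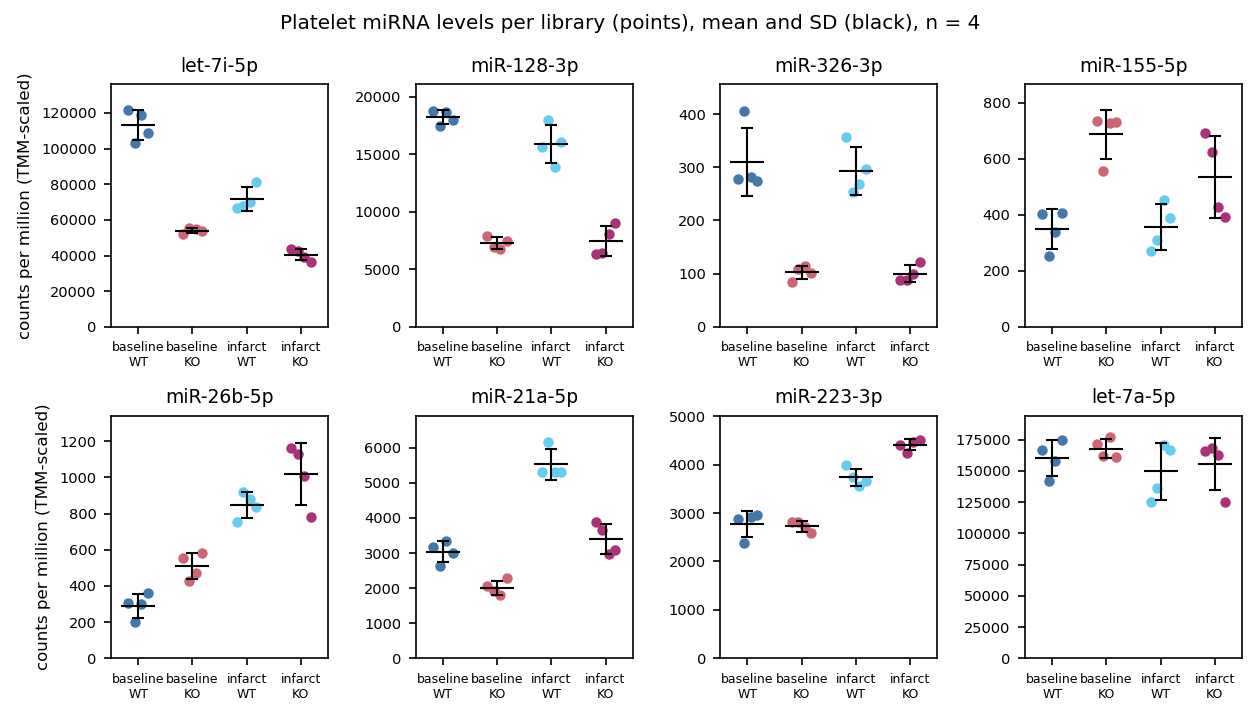
Each panel shows the level of one miRNA in CPM (library sizes scaled with TMM over all 16 libraries, axis from 0) for baseline WT, baseline KO, infarct WT and infarct KO; points are libraries, black marks the mean and bars the SD (n = 4). let-7i-5p and miR-128-3p lie lower in KO in both conditions (miR-128-3p at 18231 and 7269 CPM at baseline, 15885 and 7459 CPM after infarct), and miR-26b-5p and miR-21a-5p lie higher after infarct in both genotypes.

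The second comparison asked what an infarct changes in WT platelets. Whether infarct and baseline libraries were prepared together is not given, so every fold change of infarct here and in KO holds any difference in preparation too. miR-26b-5p, which lies in an intron of Ctdsp1, rose 2.91-fold from 294 ± 63.1 to 857 ± 93.9 CPM, and miR-21a-5p rose 1.81-fold from 3080 ± 209 to 5570 ± 519 CPM (SD, n = 4). The granulocyte and platelet miRNA miR-223-3p rose 1.34-fold from 2816 ± 209 to 3761 ± 97.9 CPM (SD, n = 4). miR-339-5p fell 2.72-fold from 487 ± 121 to 179 ± 12.2 CPM, and miR-25-3p fell 1.93-fold from 3812 ± 226 to 1980 ± 100.5 CPM (SD, n = 4). The red cell miRNA miR-486a-5p, counted identically to miR-486b-5p, fell 2.71-fold from 1139 ± 579 to 421 ± 214 CPM (SD, n = 4; adjusted p = 0.0201).

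All 4 infarct libraries lay above the baseline median for each rise named here and below it for each fall. The rises on the log2 scale were 1.54 ± 0.15 for miR-26b-5p (adjusted p = 6.52e-05), 0.85 ± 0.09 for miR-21a-5p, 0.85 ± 0.11 for miR-34a-5p, 0.85 ± 0.18 for miR-152-3p, 0.84 ± 0.13 for miR-151-5p and 0.77 ± 0.08 for miR-674-5p. Smaller rises were seen for miR-322-5p, which shares the seed of miR-16 (0.71 ± 0.08), miR-222-3p (0.70 ± 0.13), miR-27b-3p (0.59 ± 0.14) and miR-18a-5p (0.57 ± 0.14). The falls were -1.44 ± 0.15 for miR-339-5p (adjusted p = 6.52e-05), -1.44 ± 0.39 for miR-486a-5p and miR-486b-5p, -1.16 ± 0.18 for miR-340-5p, -1.07 ± 0.15 for miR-361-3p and -0.97 ± 0.19 for miR-148a-3p. Smaller falls were -0.94 ± 0.08 for miR-25-3p, -0.92 ± 0.17 for miR-1843a-3p, -0.76 ± 0.15 for miR-30d-5p and -0.75 ± 0.11 for let-7d-3p. Of the abundant miRNAs, let-7i-5p (-0.67 ± 0.09), miR-328-3p (-0.55 ± 0.15), let-7f-5p (-0.47 ± 0.13) and miR-191-5p (-0.38 ± 0.10) fell and miR-26a-5p rose (0.45 ± 0.10). let-7a-5p (-0.11 ± 0.12), let-7c-5p (-0.14 ± 0.13), let-7b-5p (-0.13 ± 0.11), miR-16-5p (-0.12 ± 0.10) and miR-128-3p (-0.21 ± 0.09) did not pass. The muscle miRNA miR-1a-3p fell (-0.89 ± 0.23), and miR-122-5p (0.34 ± 0.28), miR-150-5p (-0.03 ± 0.12), miR-126a-3p (-0.26 ± 0.09, adjusted p = 0.0541) and miR-451a (-0.59 ± 0.98) did not pass. Mir26b lies on chromosome 1 from 74394310 to 74394394, and Mir486 on chromosome 8 from 23142555 to 23142682 in an intron of Ank1. Mir25 lies on chromosome 5 from 138165321 to 138165404 within Mcm7. An exon of some annotated Mcm7 transcript overlaps it, which leaves open an intron of other transcripts.

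No list passed camera after infarct in WT (0 of 18; 0 with an estimated correlation, 5 with fry), while several held calls. Of 25 platelet miRNAs 9 were higher, among them miR-21a-5p, miR-223-3p, miR-26a-5p and miR-27b-3p, 4 lower and 12 not passing, with 9 and 7 adjusted over the list alone (camera adjusted p = 0.378). In the miR-23, miR-27 and miR-24 clusters 4 of 7 were higher (miR-27b-3p, miR-23a-5p at 0.56 ± 0.16, miR-27a-3p at 0.51 ± 0.11 and miR-23a-3p at 0.35 ± 0.10) and 0 lower, with 5 higher adjusted over the list alone (0.158). The miR-17 to miR-92 clusters split, with miR-106a-5p (0.75 ± 0.17) and miR-18a-5p higher and miR-25-3p, miR-17-3p (-0.63 ± 0.17), miR-17-5p (-0.61 ± 0.11) and miR-92a-3p (-0.52 ± 0.09) lower of 15 (0.824). Adjusted over the list alone 4 members of these clusters were higher and 4 lower. In the inflammation and hypoxia list miR-21a-5p, miR-34a-5p and the hypoxia-induced miR-210-3p (0.41 ± 0.13) were higher, 0 lower and 6 not passing, with 3 and 1 adjusted over the list alone (0.202). Among let-7 guide strands let-7d-5p (0.42 ± 0.09) and let-7g-5p (0.48 ± 0.09) rose while let-7i-5p and let-7f-5p fell and 5 did not pass (0.816). The family of miR-15 and miR-16 had miR-195a-5p (0.81 ± 0.19) and miR-15a-5p (0.70 ± 0.20) higher of 5 (0.158), the miR-29 family miR-29a-3p (-0.58 ± 0.09) lower of 3 (0.378) and the miR-30 family miR-30d-5p lower of 7 (0.497). The miR-99, miR-100 and miR-125 list had miR-125a-5p (-0.52 ± 0.10) and miR-125b-5p (-0.54 ± 0.08) lower of 4 (0.158).

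Both myeloid calls were upward, miR-223-3p (0.42 ± 0.08) and miR-223-5p (0.45 ± 0.10) of 5 (0.197). Of 8 red cell miRNAs 2 were lower, the identical miR-486a-5p and miR-486b-5p, and 2 were lower adjusted over the list alone (0.158). Of 6 lymphocyte miRNAs miR-181a-5p (-0.32 ± 0.09) and miR-342-3p (-0.87 ± 0.21) were lower (0.418), and of 3 liver miRNAs miR-194-5p was higher (0.80 ± 0.24; 0.158). Of 2 muscle miRNAs miR-1a-3p was lower, of 4 endothelial miRNAs miR-222-3p was higher, with 1 higher and 1 lower adjusted over the list alone (0.816), and of 2 stromal miRNAs 0 passed. In the Sfmbt2 cluster 4 of 44 were lower, 2 adjusted over the list alone (0.824), and its camera direction (down) differed from its mean of 0.01. Of 7 miRNAs made without Drosha miR-320-3p was higher (0.33 ± 0.08) and miR-1981-5p lower (-0.44 ± 0.10), with 2 and 2 adjusted over the list alone (0.886). Of 3 miRNAs from snoRNAs 0 passed (0.816), with a median of -0.04, a mean of 0.01 and an upward camera direction, and of 4 Dlk1-Dio3 miRNAs 0 passed (0.631).

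edgeR's test called 38 miRNAs higher and 46 lower of 443 after infarct in WT, and 104 (23.5%, chance 2.86%) did not overlap between groups. Of the calls 15 changed more than 2-fold, 6 of them with a mean of at least 100 CPM. Higher calls made up 45.2% with TMM and 75.0% with library totals only. Library totals shift the median by 0.22, leave 16 lower calls and end those of miR-486a-5p, miR-30d-5p, miR-191-5p, let-7f-5p, miR-328-3p and miR-1a-3p. Scaling to miR-451a (median shift 2.50) left 0 calls in either direction and put every fall named here above 0, among them miR-25-3p at 1.63. The call of miR-486a-5p also ended without baseline WT 4, infarct WT 2, infarct WT 3 or infarct WT 4. With a library left out, 18 of the 43 list members that passed lost their call at least once, among them miR-181a-5p, miR-194-5p, miR-210-3p, miR-15a-5p, miR-17-3p, miR-23a-3p, miR-23a-5p and miR-1a-3p.

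The third comparison asked what an infarct changes in KO platelets. miR-322-5p rose 2.34-fold from 661 ± 56.8 to 1550 ± 24.4 CPM, and miR-26b-5p rose 2.003-fold from 503 ± 68.8 to 1008 ± 175 CPM (SD, n = 4). miR-21a-5p rose 1.69-fold from 1989 ± 197 to 3361 ± 465 CPM, and miR-223-3p 1.61-fold from 2700 ± 109 to 4358 ± 92.1 CPM (SD, n = 4). miR-181d-5p fell 2.37-fold from 194 ± 21.8 to 81.8 ± 16.2 CPM, and miR-25-3p 1.67-fold from 5520 ± 440.5 to 3304 ± 175 CPM (SD, n = 4).

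Every infarct library lay on the same side of the baseline median for the changes named here. The rises on the log2 scale were 1.23 ± 0.11 for miR-322-5p (adjusted p = 3.80e-05), 1.09 ± 0.24 for miR-301a-3p, 1.002 ± 0.16 for miR-26b-5p, 0.96 ± 0.22 for miR-106a-5p, and 0.96 ± 0.14 for miR-151-5p. Smaller rises were 0.78 ± 0.20 for miR-18a-5p, 0.77 ± 0.14 for miR-22-3p, 0.76 ± 0.12 for miR-21a-5p, 0.75 ± 0.17 for miR-223-5p and 0.72 ± 0.17 for miR-23b-3p. The falls were -1.24 ± 0.18 for miR-181d-5p (adjusted p = 0.00135), -1.16 ± 0.35 for miR-148a-3p (0.0476), -0.93 ± 0.13 for let-7d-3p, and -0.74 ± 0.10 for miR-25-3p. Smaller falls in KO were -0.68 ± 0.18 for miR-339-5p, -0.63 ± 0.15 for miR-10a-5p, -0.61 ± 0.16 for miR-3074-5p, -0.59 ± 0.16 for miR-466f-3p, -0.58 ± 0.17 for miR-466i-5p and -0.58 ± 0.11 for miR-196b-5p. miR-223-3p (0.69 ± 0.09) and miR-26a-5p (0.52 ± 0.09) rose, and let-7f-5p (-0.54 ± 0.16), let-7c-5p (-0.42 ± 0.10) and let-7i-5p (-0.42 ± 0.08) fell. let-7a-5p (-0.11 ± 0.10), let-7b-5p (-0.32 ± 0.13), miR-191-5p (0.17 ± 0.11), miR-16-5p (0.26 ± 0.09, adjusted p = 0.0876), miR-328-3p (-0.06 ± 0.17) and miR-128-3p (0.03 ± 0.12) did not pass. Nor did miR-126a-3p (0.00 ± 0.12), miR-150-5p (0.06 ± 0.14), miR-122-5p (-0.40 ± 0.50), miR-1a-3p (-0.93 ± 0.46) or miR-451a (-0.26 ± 1.302). Mir322 lies on chromosome X from 53054255 to 53054349 on the minus strand with no annotated host gene.

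In KO platelets, 3 lists passed camera upward after infarct and none kept its call with an estimated correlation. Of 25 platelet miRNAs 7 were higher, among them miR-22-3p, miR-21a-5p, miR-223-3p and miR-26a-5p, 2 lower and 16 not passing. Adjusted over the list alone 9 platelet miRNAs were higher and 2 lower (camera adjusted p = 0.0237; adjusted p = 0.286 with an estimated correlation). Of the miR-23, miR-27 and miR-24 clusters 4 of 7 were higher (miR-23a-5p at 1.28 ± 0.29, miR-23b-3p, miR-23a-3p at 0.43 ± 0.13 and miR-27a-3p at 0.36 ± 0.10), 0 lower and 6 higher adjusted over the list alone (0.0237; adjusted p = 0.321 with an estimated correlation). Of the miR-15 and miR-16 family miR-195a-5p (0.77 ± 0.23) and miR-15a-5p (0.65 ± 0.19) were higher, 0 lower and 3 higher adjusted over the list alone of 5 (0.0400; adjusted p = 0.296 with an estimated correlation). The miR-17 to miR-92 clusters had 4 of 15 higher (miR-106a-5p, miR-18b-5p at 0.88 ± 0.24, miR-18a-5p and miR-93-5p at 0.48 ± 0.09) and miR-25-3p lower, with 4 and 2 adjusted over the list alone (0.589). In the inflammation and hypoxia list miR-21a-5p, miR-21a-3p (2.22 ± 0.48) and miR-34a-5p (0.63 ± 0.18) were higher of 9, with 4 higher adjusted over the list alone (0.172). Of 9 let-7 guide strands let-7d-5p (0.50 ± 0.08) rose, let-7c-5p, let-7i-5p and let-7f-5p fell and 5 did not pass (0.464).

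Liver miRNAs miR-192-5p (1.13 ± 0.26) and miR-194-5p (1.04 ± 0.24), which share a transcript, were higher of 3 (0.172), although miR-122-5p did not pass. Both arms of miR-223 were higher of 5 myeloid miRNAs (0.15), of 6 lymphocyte miRNAs miR-342-3p was lower (-0.85 ± 0.21; 0.25) and of 4 endothelial miRNAs miR-221-3p was lower (-0.43 ± 0.10; 0.461). Of 7 red cell miRNAs 0 passed, 2 were lower adjusted over the list alone (0.254), with miR-486a-5p at -1.01 ± 0.32, and of 2 muscle and 3 stromal miRNAs (0.265) 0 passed. In the miR-30 family miR-30c-5p was higher (0.85 ± 0.23) of 7 (0.961), with a median of -0.09 against an upward camera direction. The miR-29 family (0.868; median -0.09, mean 0.04, camera down) and the miR-99, miR-100 and miR-125 list (0.868; median -0.04, mean 0.15, camera up) had 0 of 3 and 0 of 4 passing, the latter with 1 higher adjusted over the list alone. The Sfmbt2 cluster had 3 of 44 lower and 0 adjusted over the list alone (camera adjusted p = 0.0505). It passed downward at 0.0351 with library totals only and 0.0400 with a replicate block, but not with an estimated correlation (0.642). In the lists made without Drosha (6 tested, 0.659), from snoRNAs (3, 0.67) and in Dlk1-Dio3 (4, 0.345) 0 members passed.

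edgeR's test called 32 miRNAs higher and 20 lower of 400 after infarct in KO, and 74 (18.5%, chance 2.86%) did not overlap. Of the calls 13 changed more than 2-fold, 5 of them with a mean of at least 100 CPM. Higher calls made up 61.5% with TMM, 49.0% with counts thinned to one depth (24 higher and 25 lower), 56.0% with DESeq2 (33 lower) and 57.1% in a fit of all 16 libraries (33 lower). They made up 80.4% with library totals only (10 lower, median shift 0.11), which end those of miR-148a-3p, miR-339-5p, miR-3074-5p, miR-466f-3p, miR-466i-5p and let-7f-5p. The counts fell whichever baseline KO library was left out, and the lower power of a smaller group was not separated from the part of a single library. They were 7 higher and 6 lower without baseline KO 4 and 10 and 8 without baseline KO 2. Without baseline KO 3 they were 14 and 10, and without baseline KO 1 14 and 14. They were 21 and 10 without infarct KO 3, 13 lower without infarct KO 2 and 49 higher without infarct KO 1. Of the 32 list members that passed, 26 lost their call at least once, among them miR-192-5p, miR-194-5p, miR-15a-5p, miR-195a-5p, miR-23a-3p, miR-27a-3p, miR-34a-5p, miR-342-3p and miR-30c-5p.

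**Figure D2:**
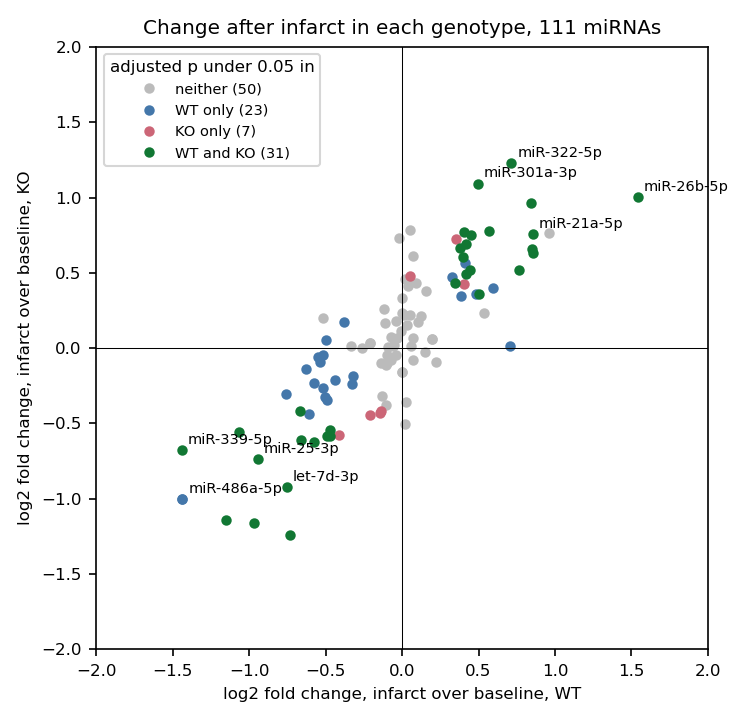
Each point is one of 111 miRNAs above 100 CPM, with its log2 fold change of infarct over baseline in WT on the x axis and in KO on the y axis; colours show an adjusted p under 0.05 in neither genotype (50), WT (23), KO (7) or both (31). The points follow the diagonal with a Pearson correlation of 0.84, and no miRNA passed in opposite directions.

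The infarct responses of the genotypes, which share no library, were then compared. Over the 390 miRNAs tested in both, the log2 fold changes had a Pearson correlation of 0.41 and a Spearman correlation of 0.52 across miRNAs, which are not independent replicates, and of 0.84 (Pearson) over the 111 above 100 CPM. In a fit of all 16 libraries the Pearson correlation was 0.15. miR-26b-5p, miR-21a-5p, miR-34a-5p, miR-322-5p and miR-223-3p rose in both, and miR-25-3p, miR-339-5p, miR-148a-3p, let-7d-3p and let-7i-5p fell in both. Altogether, 23 miRNAs were higher in both, where independent lists would share 2.95, 15 were lower in both (2.36) and 0 passed in opposite directions. The expected numbers take every miRNA as equally likely to be called. In WT 24 higher and 31 lower calls fell among the 114 miRNAs with at least 100 CPM of 443 tested, so the expected numbers may be too low.

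The interaction of genotype and infarct, the test of whether these responses differ, passed for 0 of 495 miRNAs in edgeR's test, with 43 at an unadjusted p under 0.05 and a smallest adjusted p of 0.180. miR-21a-3p had the smallest p (2.24 ± 0.52), at 18.6 ± 4.15 and 18.4 ± 2.85 CPM in baseline and infarct WT and at 4.82 ± 1.82 and 22.6 ± 12.3 CPM in KO (SD, n = 4). The next were miR-322-5p (0.51 ± 0.14), miR-191-5p (0.54 ± 0.15), miR-674-3p (0.96 ± 0.27) and miR-7012-5p, which had 0 counts in all 4 infarct KO libraries, each with an adjusted p of 0.192. miR-451a (0.27 ± 1.74), miR-223-3p (0.27 ± 0.12), miR-21a-5p (-0.10 ± 0.15), let-7a-5p (-0.01 ± 0.15), let-7i-5p (0.25 ± 0.12) and miR-128-3p (0.24 ± 0.15) did not pass either. In every list 0 members passed. Adjusted over the list alone 1 platelet miRNA and 1 inflammation miRNA were higher, 1 endothelial miRNA lower and 3 members of the miR-99, miR-100 and miR-125 list higher, whose camera adjusted p of 0.111 was the smallest. For the lymphocyte list (median 0.05, camera down) and the miR-15 and miR-16 family (median -0.05, mean 0.03, camera up) the signs differed. DESeq2 called miR-21a-3p higher and miR-669d-5p and miR-7012-5p lower (named after their values were seen), limma-voom called 0. In simulated data the same fit recovered 4.92% of 1.5-fold, 25.8% of 2-fold and 46.0% of 4-fold differences of this kind among miRNAs that passed the filter. Differences of those sizes could therefore have been missed.

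The last comparison asked how KO and WT platelets differ after infarct. miR-140-3p rose 2.30-fold, at 95.9 ± 6.06 CPM in WT and 221 ± 36.5 in KO, and miR-16-5p 1.48-fold, at 97190 ± 9380 and 144277 ± 15563 CPM (SD, n = 4). miR-25-3p was 1.70-fold higher in KO, at 1965 ± 61.5 and 3345 ± 194 CPM (SD, n = 4). miR-326-3p was 2.96-fold lower in KO, at 294 ± 45.1 and 99.4 ± 15.9 CPM, and miR-128-3p 2.13-fold lower, at 15885 ± 1688 and 7459 ± 1288 CPM (SD, n = 4). miR-21a-5p was 1.63-fold lower in KO, at 5525 ± 433 and 3399 ± 438 CPM (SD, n = 4).

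On the log2 scale the largest differences upward were 1.20 ± 0.16 for miR-140-3p (adjusted p = 1.52e-05), 0.97 ± 0.23 for miR-676-3p, 0.92 ± 0.23 for miR-1306-5p, 0.82 ± 0.12 for miR-92a-3p and 0.79 ± 0.10 for miR-322-5p. Next came 0.78 ± 0.24 for miR-532-3p, 0.77 ± 0.09 for miR-25-3p, 0.71 ± 0.23 for miR-1964-3p, 0.68 ± 0.14 for miR-196b-5p and 0.66 ± 0.11 for miR-146a-5p. All 4 KO libraries lay above the WT median for these, except 3 of 4 for miR-676-3p, miR-1306-5p and miR-1964-3p. The largest downward were -1.56 ± 0.17 for miR-326-3p (adjusted p = 1.18e-06), -1.10 ± 0.10 for miR-185-5p, -1.09 ± 0.11 for miR-128-3p, -0.97 ± 0.11 for miR-27a-3p and -0.88 ± 0.19 for miR-29b-3p. Next came -0.82 ± 0.09 for let-7i-5p, -0.74 ± 0.14 for miR-151-3p, -0.71 ± 0.14 for miR-98-5p, -0.70 ± 0.11 for miR-21a-5p and -0.69 ± 0.09 for miR-103-3p, with all 4 KO libraries below the WT median. miR-191-5p (0.55 ± 0.11), miR-16-5p (0.57 ± 0.09), miR-150-5p (0.48 ± 0.14) and miR-126a-3p (0.39 ± 0.11) were higher in KO. let-7a-5p (0.06 ± 0.11), let-7c-5p (0.06 ± 0.12), let-7b-5p (0.15 ± 0.12), let-7f-5p (-0.13 ± 0.15), miR-328-3p (0.05 ± 0.17), miR-26a-5p (0.09 ± 0.09) and miR-223-3p (0.24 ± 0.09, adjusted p = 0.0583) did not pass. Nor did miR-122-5p (-0.54 ± 0.42), miR-1a-3p (0.16 ± 0.38) or miR-451a (0.57 ± 1.24). Set beside baseline in fits of separate libraries, 10 miRNAs were higher in KO in both conditions (1.73 for independent lists), 27 lower in both (4.31) and 0 opposite. The numbers for independent lists again take every miRNA as equally likely to be called and may be too low. The Pearson correlation was 0.51 and the Spearman correlation 0.56 across 408 miRNAs.

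The miR-17 to miR-92 clusters passed as a list after infarct, with 5 of 15 higher in KO (miR-92a-3p, miR-25-3p, miR-106a-5p at 0.66 ± 0.20, miR-20b-5p at 0.65 ± 0.13 and miR-93-5p at 0.56 ± 0.09), 0 lower and 5 higher adjusted over the list alone. camera gave an adjusted p of 0.0178 for it, lost with an adjusted p = 0.268 with an estimated correlation and 0.0539 with identical miRNAs counted once, a setting added after the data were seen. Of 6 lymphocyte miRNAs miR-155-5p (0.59 ± 0.20), miR-181a-5p (0.51 ± 0.10) and miR-150-5p were higher and 0 lower, with 3 adjusted over the list alone (0.0506). miR-155-5p stood at 694, 625, 430 and 393 CPM in infarct KO 1 to 4, against 270 to 454 in infarct WT. Its call ended without infarct WT 1 (0.35 ± 0.20), infarct WT 2 (0.41), infarct WT 4 (0.66), infarct KO 1 (0.43) or infarct KO 2 (0.53). The let-7 guide strands let-7i-5p, miR-98-5p and let-7e-5p (-0.52 ± 0.10) were lower, 0 of 9 higher and 5 lower adjusted over the list alone (0.149). Of 25 platelet miRNAs 8 were higher and 4 lower, 9 and 6 adjusted over the list alone (0.454). miR-27a-3p and miR-24-3p (-0.57 ± 0.10) were lower of 8 in their clusters (0.454; camera down, median -0.10, mean 0.18), and miR-15b-5p (0.57 ± 0.09) and miR-16-5p higher of 5 (0.149). Also higher were miR-30d-5p (0.52 ± 0.13) and miR-30e-5p (0.48 ± 0.14) of 7, with 3 adjusted over the list alone (0.151), and miR-125b-5p (0.53 ± 0.11) and miR-125a-5p (0.48 ± 0.11) of 4 (0.418). In the inflammation and hypoxia list miR-146a-5p, miR-155-5p and miR-34a-5p (0.45 ± 0.15) were higher and miR-21a-5p lower of 9 (0.399).

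Of the marker lists, miR-146a-5p was higher of 5 myeloid miRNAs, 2 adjusted over the list alone (0.468). miR-126a-3p was higher and miR-221-3p (-0.67 ± 0.09) lower of 4 endothelial ones (0.948; median 0.01, mean -0.05), and miR-143-3p was lower of 3 stromal ones (-1.09 ± 0.18; 0.815; camera down, median 0.22, mean 0.67). Of 8 red cell (0.399), 3 liver (0.608), 2 muscle and 4 Dlk1-Dio3 miRNAs (0.608) 0 passed, with miR-486a-5p at 1.02 ± 0.38. miR-29b-3p was the lower member of 3 in its family (0.971; median 0.19, mean -0.06). Lower too were miR-1981-5p (-0.64 ± 0.10) of 7 made without Drosha (0.528; camera down, median 0.06) and miR-1839-5p (-0.39 ± 0.13) of 3 from snoRNAs (0.468). In the Sfmbt2 cluster miR-466f-3p (0.62 ± 0.15) and miR-466i-5p (0.60 ± 0.16) were higher of 45 (0.971; median 0.07, mean -0.04).

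edgeR's test, fitted to all 16 libraries, called 46 miRNAs higher and 45 lower of 495 in KO after infarct, and 90 (18.2%, chance 2.86%) did not overlap. Of the calls 34 changed more than 2-fold, only 4 of them with a mean of at least 100 CPM. Higher calls made up 50.5% with TMM and 35.9% with library totals only (28 higher, median shift -0.09), which end those of miR-532-3p, miR-1964-3p, miR-126a-3p and miR-150-5p. A fit of the 8 libraries of the pair called 15 higher and also lost miR-676-3p and miR-1306-5p, and the higher count was 30 with identical miRNAs counted once, 25 with counts thinned to one depth, 20 without infarct WT 2 and 30 without infarct KO 4. With a library left out, 13 of the 34 list members that passed lost their call at least once, among them miR-150-5p, miR-106a-5p, miR-126a-3p, miR-30d-5p, miR-30e-5p, miR-34a-5p, miR-125a-5p, miR-125b-5p and miR-1839-5p.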

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

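In a group of 4 libraries, a library was picked out when its gap to the nearest other exceeded the 95% value of Dixon's test. This was asked of 79 measures in 316 groups; 23 groups had such a library, where chance alone gives 15.8. With miRNAs of identical counts taken once, 22 of 312 groups had one, against 15.6 by chance. Levels here are CPM scaled over all 16 libraries, with the range of the other 3 libraries in brackets. Baseline WT 2 was low for miR-16-5p at 92792 (108373 to 109866), miR-223-3p at 2382 (2869 to 2950), miR-98-5p at 809 (1052 to 1100) and the red cell miR-144-3p at 0.505 (2.98 to 3.65), and high for miR-326-3p at 406 (274 to 282). Infarct WT 1, with the fewest counts of its group, was low for miR-146a-5p at 242 (300 to 313) and miR-1843a-3p at 53.2 (74.6 to 78.4), and high for miR-339-5p at 204 (168 to 172) and miR-484 at 158 (120 to 124). Infarct WT 2 was high for miR-21a-5p at 6175 (5298 to 5319), miR-25-3p at 2056 (1924 to 1943) and miR-3074-5p at 210 (174 to 178). Infarct KO 4, the library with the fewest counts of all, was low for let-7a-5p at 125010 (162752 to 168571) and high for miR-152-3p at 173 (130 to 135). Baseline KO 3 was high for let-7c-5p at 224488 (168775 to 174905) and for the share of the 10 most abundant miRNAs at 86.6% (85.2 to 85.4). Infarct KO 3 was low for the identical miR-486a-5p and miR-486b-5p at 376 (989 to 1042). In other libraries, miR-103-3p was low in baseline WT 4 at 9025 (10454 to 10646), miR-155-5p in baseline KO 2 at 556 (727 to 735) and miR-182-5p in baseline KO 4 at 0.151 (2.34 to 2.84). miR-191-5p was high in baseline KO 1 at 126083 (100432 to 104203) and miR-31-5p in infarct WT 4 at 321 (270 to 277).

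The tests of the next 3 patterns, and the divisions of the libraries after them, were chosen after the results were seen. miR-486a-5p was lower after infarct in WT (-1.44 ± 0.39), and red cell RNA carried over in different amounts is a candidate explanation. Within groups, miR-486a-5p followed the mean of the other red cell miRNAs over 16 libraries with r = 0.774 (adjusted permutation p = 0.00716). Carry-over would give such a relation between libraries of one group. Deviations from group means leave out the difference between infarct and baseline, so this r cannot say whether carry-over made the fall. Without the 2 farthest libraries r was 0.749. The adjustment covers Pearson and Spearman, within groups and over all libraries. It does not cover the choice from 30 pairs of such miRNAs looked at. Member by member r was 0.71 for miR-451a, 0.83 for miR-144-5p, 0.47 for miR-144-3p and 0.00 for miR-182-5p, so the relation was not held by every member. These members lay near the floor. Scaled over all 16 libraries, their highest levels were 8.77, 25.01, 5.85 and 3.69 CPM in that order. Their lowest were 0 CPM, and 0.149 CPM for miR-144-5p. How the kit and the mapping treat red cell miRNAs is not given in the sources used here, so their levels do not measure red cell content. With library totals only the log2 fold change of miR-486a-5p was -1.17 (edgeR, adjusted p = 0.0608), a shift of 0.268 that lies within its SE of 0.385. TMM factors therefore make up only part of the fall, although the call was lost. Scaling to miR-451a put it at 0.93, but on 1 to 48 counts, so scaling in general cannot be told from a real fall. An effect of the infarct itself stays open, as no label separates it from differences in cell purity or preparation.

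More miRNAs were lower than higher after infarct in WT, 46 against 38, but the excess was small and turned with single libraries. There were 32 higher and 31 lower without baseline WT 4, 34 and 32 without infarct WT 2, 39 and 38 without infarct WT 3, and 30 and 29 among miRNAs with at least 100 CPM. With library totals only, 75.0% of the calls were higher, so the excess could come from the scaling: TMM factors were 0.87 to 0.98 at baseline and up to 1.20 after infarct. With counts thinned to one depth 42.05% were higher, which decides nothing about depth for an excess that single libraries turn. Whether platelets lose or gain miRNA in all after an infarct stays open.

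Of the 10 most abundant miRNAs, let-7i-5p, miR-128-3p and miR-328-3p fell and let-7b-5p and let-7c-5p rose in KO at baseline. The other 5 did not pass, among them let-7a-5p at 0.08 ± 0.08 and miR-191-5p at 0.03 ± 0.09. A loss common to all Dicer products might be taken out by scaling, and would raise the share of miR-451a, which needs no Dicer. Its log2 ratio of KO over WT was 0.371 (exact permutation p = 0.629; -0.299 to 0.967 with a library left out), which cannot tell the explanations apart at 0 to 75 counts per library. The falls of let-7i-5p (2.07-fold) and miR-128-3p (2.48-fold) beside let-7a-5p argue against a loss of the same size for all. How much miRNA a KO platelet holds stays open.

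The labels of the libraries were also divided in every other way of 4 against 4. Of 35 divisions, 1 (the true one) called as many miRNAs as the real comparison for KO against WT at baseline (102 calls, at most 0 in another), infarct in WT (84, at most 2), infarct in KO (52, at most 1) and KO against WT after infarct (91, at most 30). A batch that coincided with infarct or genotype would do the same, so these divisions speak to chance alone. The labels name no batch, and infarct and such a batch cannot be told apart, also where both genotypes changed alike. For the interaction, 0 calls fix the outcome (100 of 100 drawn divisions call at least 0), so this says nothing about chance. The most calls were 69, in a draw that swaps genotype at baseline and so turns the genotype effect into an interaction.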

How the results depend on the processing

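For named miRNAs under the alternatives, call status was unchanged in 3017 cases, a call was gained in 23 and lost in 179. In 15 cases the sign reversed with a call in either fit. A miRNA without a call in both fits counts as unchanged whatever its size or sign, as for most of the interaction. These counts therefore follow calls and not effect sizes. All reversals came from scaling to miR-451a in infarct against baseline in WT, which moved the median by 2.50 on 1 to 48 counts and left 0 higher and 0 lower calls: miR-339-5p 0.78, miR-486a-5p and miR-486b-5p 0.93, miR-340-5p 1.82, miR-361-3p 1.17, miR-148a-3p 2.08, miR-25-3p 1.63, miR-1843a-3p 1.66, miR-30d-5p 1.48, let-7d-3p 1.92, let-7i-5p 1.88, miR-191-5p 2.02, let-7f-5p 2.33, miR-328-3p 1.69 and miR-1a-3p 1.98. It could not be run in the other comparisons, where 1 or 2 libraries have 0 such counts. For KO against WT at baseline, 31 were lower with at least 100 CPM (fewer miRNAs tested) and 25 higher in a fit of all 16 libraries, and leaving out a library gave 37 to 51 higher and 43 to 60 lower. For infarct in WT, 16 were lower with library totals only and 29 with at least 100 CPM, and leaving out a library gave 27 to 39 higher and 31 to 46 lower. For infarct in KO, counts thinned to one depth gave 24 higher and 25 lower, so the excess of higher calls was not kept, 10 were lower with library totals only, 33 with DESeq2 and 33 in a fit of all 16 libraries; leaving out a library gave 7 to 49 higher and 6 to 27 lower, the least without baseline KO 4 and the most without infarct KO 1. KO against WT after infarct had 28 higher with library totals only, 15 in a fit of 8 libraries, 30 with identical miRNAs counted once and 25 with counts thinned, the last 2 chosen after the data were seen, and 20 (without infarct WT 2) to 52 (without infarct KO 2) higher and 39 to 51 lower with a library left out. The interaction had 0 higher and 2 lower without a filter (miR-6238 and miR-6240), 1 and 2 with DESeq2, 2 and 0 without infarct KO 1 (miR-21a-3p and miR-674-3p), and 1 and 1 without infarct KO 4 (miR-21a-3p and miR-3076-5p). Lists called numbered 0 in every comparison with an estimated correlation, against 1, 0, 3, 1 and 0 in the order above, and 9, 5, 8, 8 and 0 with fry. At baseline 0 lists passed with a replicate block, in KO 4 passed after infarct with a replicate block and 4 with library totals only (the Sfmbt2 cluster downward added), in WT 1 passed with scaling to miR-451a (red cell, downward), and for KO against WT after infarct 3 passed with library totals only (lymphocyte and miR-17 to miR-92 upward, let-7 downward) and 0 with identical miRNAs counted once. The correlation of infarct responses was 0.84 with at least 100 CPM, 0.15 in a fit of all 16 libraries, and 0.30 to 0.41 with a library left out. The replicate number was blocked too, with 44 and 54, 32 and 46, 36 and 28, 41 and 39, and 0 and 0 calls higher and lower. Of 24 pairs with the same number 1 had r above 0.1 (-0.115 to 0.223), so the numbers show no pairing over all groups. That pair joined baseline KO and infarct KO, where same-number pairs ran from 0.0261 to 0.223. A pairing of these groups cannot be excluded. With the block, their 32 higher and 20 lower calls became 36 and 28. Where no cause is given, the cause was not tested. What depth alone limits was not separated from the spread between libraries. In simulated data 1.5-fold changes were recovered for 42.6%, 36.1%, 28.6%, 23.0% and 4.92% of the changed miRNAs that passed the filter, in the order above.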

Other observations

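Both arms of a hairpin come from one precursor. Changes in transcription, or in the cutting of the precursor by Dicer, could move them together, and changes in stability of a single arm would not. A correlation of the arms cannot separate transcription from cutting. The permutation p of arms and of neighbouring hairpins come from shuffling hairpins read in the same libraries. Hairpins are not independent replicates, so these p do not measure the spread between libraries. The tests of arms and of let-7d here were chosen after the results were seen; that of neighbouring hairpins was not, except over all hairpins and without the Sfmbt2 cluster. With at least 10 CPM in both arms, log2 fold changes of the arms correlated at r = 0.662 for KO against WT at baseline (45 hairpins, permutation p = 1e-05, the smallest possible), 0.272 for infarct in WT (46, permutation p = 0.0681), 0.338 for infarct in KO (45, permutation p = 0.0240, adjusted 0.0601) and 0.576 for KO against WT after infarct (45, permutation p = 5e-05). Over all hairpins r was 0.381, 0.0755, 0.190 and 0.130 (permutation p = 0.00019, 0.466, 0.0832 and 0.155), and the minimum of 10 CPM was chosen after both were seen. For KO against WT after infarct over all hairpins the Spearman correlation was 0.233 (permutation p = 0.0149, adjusted 0.0373), so Pearson and Spearman differ there and the relation stays open. Without the Sfmbt2 cluster and with identical miRNAs taken once, the correlations at 10 CPM were 0.686, 0.229, 0.347 and 0.579. Where both arms passed, 11 hairpins went the same way and 0 opposite at baseline, 7 and 1 in infarct WT, 3 and 1 in infarct KO, and 7 and 0 for KO against WT after infarct.

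Hairpins within 10000 bp of each other, which often share a transcript, had a mean absolute difference in log2 fold change of 0.368 for KO against WT at baseline (shuffled median 0.655, 39 pairs, permutation p = 6e-04) and 0.383 after infarct (0.737, 41 pairs, permutation p = 5e-04). For infarct the differences were 0.529 in WT (0.686, permutation p = 0.101) and 0.567 in KO (0.609, permutation p = 0.316). Over all hairpins the differences were 0.422 for KO against WT at baseline (shuffled median 0.848) and 0.565 after infarct (1.38), each with the smallest possible permutation p of 0.0001. For infarct they were 0.597 in WT (0.867, permutation p = 0.0118, adjusted 0.0189) and 0.641 in KO (0.776, permutation p = 0.0797). Members of the Sfmbt2 cluster are neighbours and alike in sequence, so the test was repeated without them and with identical miRNAs taken once. The differences at 10 CPM were then 0.384 for KO against WT at baseline (0.667, 32 pairs, permutation p = 0.0027) and 0.393 after infarct (0.757, 34 pairs, permutation p = 0.0013). For infarct in WT they were 0.558 (permutation p = 0.168) and 0.665 over all hairpins (permutation p = 0.0659), and in KO 0.626 (0.604, permutation p = 0.590), so the relation stays open there. A change in which precursors are made could explain why neighbours move together in KO platelets at baseline (0.368), but precursors were not analysed here.

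let-7d-5p rose after infarct in WT (0.42 ± 0.09) and KO (0.50 ± 0.08) while its other arm let-7d-3p fell (-0.75 ± 0.11 and -0.93 ± 0.13). If let-7d-5p were counted with reads of other let-7 members it would follow them. Their medians were -0.12 in WT and -0.22 in KO, but let-7g-5p, at 0.48 in WT and 0.36 in KO, lay within 0.520 and 0.793 SE of the difference from let-7d-5p, so shared reads stay open. The share of the let-7 family, chosen after the data were seen, differed by -7.67 percentage points between infarct and baseline KO and by -6.09 between KO and WT after infarct (exact permutation p = 0.0286 each, the smallest possible, adjusted 0.0571). It differed by 0.587 between KO and WT at baseline and by -0.989 after infarct in WT (exact permutation p = 0.686 and 0.6). Relations of fold change with mature length and level numbered 20, with Spearman correlations of -0.203 to 0.0946 and 0 at an adjusted p under 0.05.

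The libraries of infarct KO were uneven. The chi-square per degree of freedom was 130 between infarct KO 1 and 2 and 137 between 3 and 4, against 764, 889, 416 and 629 for the other pairs. On the third principal component infarct KO 1 to 4 lay at -17.4, -11.9, 8.09 and 7.15. No deposited label accounts for this. Infarct KO 1 and 2 held 9.66 and 9.88 M counts, against 6.83 and 3.74 M in infarct KO 3 and 4. The chi-square also depends on depth, being larger at more counts for the same spread, yet the deepest pair, infarct KO 1 and 2, had the lowest. The SD of log2 ratios between libraries was 0.64 for infarct KO 1 and 2 and 0.55 for 3 and 4. It was 0.77 to 0.90 for the other pairs. These values argue against the depth dependence of the chi-square as the source of the split. Other effects of depth were not tested. Such effects of depth and an unrecorded difference in preparation both stay open, and the libraries were not divided by the split.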
